A study of Mus musculus with 2 samples.

How the data were processed

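H3K36me3 ChIP-seq was done on liver from B6NCrl mouse embryos at embryonic day 12.5, in 2 biological replicates with a library size range of 300 to 500 bp, per the labels. Each replicate is a pool of livers, from 120 and 88 embryos of both sexes. The p-values below therefore measure how genes, lists or positions differ within these pools, not the variation between animals.

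The files used were 4 peak lists on mouse build mm10, described in text files deposited with them. The authors called peaks on each replicate's own alignments, on both replicates' alignments together (the pooled list), and deposited a replicated list derived from these. Replicate 1 and the pooled list were called against 2 control files and replicate 2 against 1, per the deposited description, so part of any difference between the replicates' lists can come from their controls. The aligner, the peak caller, their versions and the rule for replication are not given in the sources used here. Each peak carries a signal value from the authors, taken here as a linear ratio (fold enrichment over control), whose scaling is not given in the sources used here. It was used to describe, rank or weight peaks within a list and, in the closing section, to compare X with autosomes within each list. Fold-weighted coverage of genes was also averaged over the 2 replicate lists, and genes were ranked by that mean. Folds of the 2 replicates are printed side by side, and a difference between them can come from that scaling. Each peak also carries the authors' −log10 p-value and −log10 q-value. No deposited −log10 p was under 2.02, which matches a p threshold of 0.01. Such a loose threshold admits weak peaks, so stricter ones were tried. The lists are of the narrow peak type. A broad domain of H3K36me3 is therefore broken into many rows, and counts of peaks say less than covered bases. Control samples were not analysed here. The number of reads behind each list is unknown here, so no value was corrected for depth and differences in covered bases between replicates may reflect depth.

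Gene positions came from the GENCODE mouse release 21 annotation of GRCm38, the same build as mm10, and chromosome lengths and sequenced (non-N) bases from the RefSeq assembly of that build. No peak reached past a chromosome end, and no rows overlapped within a list. Autosomes, X and Y were used. Peaks on unplaced scaffolds or on scaffolds with no position within their chromosome, 18 in replicate 1 and 21 in replicate 2, were left out of the comparisons. A gene body ran from the annotated start to the annotated end of a protein-coding gene (21938 genes). Its measure was the percent of bases covered by a list, and a gene was called marked when at least 20% was covered in each replicate list. Coverage does not use strand, so overlapping or closely spaced genes share it. For that reason 1649 genes with at least 50% of their body inside another protein-coding gene were left out of the named genes, and out of all genes in 1 alternative. Values are means over the replicates with the SD (n = 2).

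Overlap between replicates was the percent of bases covered by either list that both covered. It and the share of covered bases in genes were compared with circular shifts of a list within each chromosome, in a number that allows a smallest p of 0.001 (one-sided). Profiles used 20 equal bins per marked gene of at least 10 kb, and the first 5 were compared with the last 5. Exonic bases were the union of exons of protein-coding transcripts, without the first exon of any such transcript. Bases between the exons of these transcripts counted as intronic, first introns included. With 1 group of 2 samples there is no test between groups, so the profiles and exon shares were compared with the spread between replicates alone.

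Before the data were examined, 34 gene lists were fixed, with 8 of liver cell types, 1 of adult hepatocyte metabolism, 9 of other tissues and 16 of gene classes. Of the listed symbols, 6 had no protein-coding gene in the annotation, among them alternative names of the same gene. The number of marked members was compared with 10000 random lists of the same size drawn from all protein-coding genes within 20 length classes (two-sided, Benjamini-Hochberg over the 34 lists, threshold 0.05). Differences between kinds of list and between X and autosomes were tested with 100000 resamples of the labels within length classes, and the fetal against adult hepatocyte lists with 100000 resamples over their genes. Genes are the units of these tests, and neighbouring or co-regulated genes are not independent, so the p-values can be too small. The functions were tested on simulated data first. Over 600 unchanged lists, 21 passed an unadjusted p of 0.05. Of 200 lists of 20 genes with the marked share doubled, 172 passed, and all 200 passed with the share set to 0. Of 200 unchanged differences between labels, 7 passed. Marks in these simulated lists and labels were drawn independently for each gene, so they do not measure the effect of neighbouring or co-regulated genes. In the test against circular shifts, 2 of 20 lists placed at random passed a p of 0.05.

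Genes named in the text were picked by a rule fixed before the data were examined. It takes, for each cell type or tissue list, the 2 members with the highest and the 1 with the lowest mean percent covered, and for each gene class the 1 highest and the 1 lowest, with ties settled by symbol. Over all genes of at least 10 kb it takes the 10 with the highest fold-weighted coverage (fold times covered bases, summed over the gene and divided by its length) and the 5 with the largest difference between replicates. Genes at least 50% inside another protein-coding gene were left out of these picks. Picks could be left out of the text, and any gene named outside the rule is said to have been chosen after its values were seen.

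Alternatives were peaks with −log10 q of at least 2 or −log10 p of at least 5, marking at 10% or 40% of the body, the replicated list alone, each replicate left out, other rules for shared peaks, rows within 1000 bp merged, the pooled list or all annotated genes for the genic share, genes of at least 10 kb for the rank correlation and at least 30 kb for the profile, genes inside other genes left out, and genes of at least 2 kb alone. Analyses used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures matplotlib 3.10.9.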

Results

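Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark laid down on the bodies of transcribed genes, was profiled by chromatin immunoprecipitation and sequencing in the liver of mouse embryos at day 12.5 of development. The liver at this stage holds hepatoblasts, the precursors of hepatocytes, together with the blood-forming cells that colonise it. The samples formed 1 group of 2 biological replicates, a pool of livers from 120 embryos of both sexes (replicate 1) and a pool from 88 embryos of both sexes (replicate 2). Replicate 1 had 151033 peaks covering 128 Mb and replicate 2 had 145471 peaks covering 136 Mb, a mean of 132 Mb ± 5.53 (SD, n = 2). The median fold enrichment per peak, a value given by the authors for each peak, was 3.03 in replicate 1 and 3.32 in replicate 2. The read depth of both libraries is unknown here, so no interval that needs depth is given. With no treated or control group, the comparisons were between the replicates, between parts of the genome, and between groups of genes within the same samples.

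The pools covered largely overlapping sets of genes and bases. Of the genes with at least 20% of the body covered, 7123 in replicate 1 and 7304 in replicate 2, 7015 were shared. Across 21938 protein-coding genes, the percent of the gene body covered by peaks had a Spearman rho of 0.978 between the replicates, a correlation across genes, which are not independent replicates. Top2a, the topoisomerase that untangles replicated DNA, was covered over 97.0% of its body in replicate 1 and 96.1% in replicate 2. Gfi1b, a transcription factor of red cell and platelet precursors, was covered over 73.5% and 73.8%. The genes of at least 10 kb that differed most between the pools were Htatsf1 (33.1% in replicate 1 and 56.3% in replicate 2), Hsd17b7 (37.6% and 57.0%), Zfp189 (37.4% and 56.8%), Bcl10 (29.9% and 48.6%) and Zfp12 (63.8% and 82.0%), each more covered in replicate 2. The same direction held for 5310 of the 7015 marked genes (75.7%), with a mean difference of 2.49 percentage points. Of all bases covered in either replicate, 71.0% were covered in both. Lists shifted at random along each chromosome gave a mean of 2.86% and at most 4.47% (one-sided permutation p = 0.001, the smallest the shifts can give). Among single peaks, 81.5% of those of replicate 1 and 77.0% of those of replicate 2 touched a peak of the other by at least 1 bp, a mean of 79.3% ± 3.14 (SD, n = 2). When at least 50% of both peaks had to overlap, the mean was 48.7%. Unshared peaks were shorter, with median lengths of 256 bp against 525 bp for shared peaks in replicate 1 and 261 bp against 588 bp in replicate 2. Their median fold was 2.52 against 3.21 for shared peaks in replicate 1, and 2.78 against 3.61 in replicate 2. The authors' replicated list kept 110796 of the 148356 peaks called on both replicates pooled and 93.4% of their covered bases. The dropped peaks had a median length of 245 bp and a median fold of 2.20, against 678 bp and 3.18 for those kept.

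H3K36me3 lay almost wholly within genes. Protein-coding gene bodies held 94.8% of the bases of the replicated list, although they make up 39.3% of the sequenced genome. Random shifts of the list gave a mean of 40.9% and at most 44.4% (one-sided permutation p = 0.001, the smallest the shifts can give). The share was 94.8% in replicate 1 and 94.9% in replicate 2. The peak with the highest fold in the authors' deposited replicated list, at 23.2, spanned 7.67 kb of chromosome 8 (122332650 to 122340314, mm10). It lay wholly within Gm20388, and 60.0% of it lay in Zfpm1, which encodes the GATA1 cofactor FOG1. The next in that list, at a fold of 20.5, lay on chromosome 7 (5027324 to 5034215) within Zfp865 and Ccdc106. Peaks with folds of 20.3 in Ccnf (cyclin F), 19.08 in Trim56 and 19.06 in Srrm2, a splicing factor gene, followed in the same deposited list. Apart from Ccnf, the genes named for these peaks were chosen after their values were seen.

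Within genes, coverage was low at the 5′ end and climbed toward the 3′ end. In 5164 marked genes of at least 10 kb, where marked means at least 20% of the body covered in each replicate, the bin at the 5′ end was covered over 4.63% ± 0.300 of its bases (SD, n = 2; 20 equal bins per gene). Coverage was highest in bin 18, at 74.5% ± 2.14, and was 65.6% ± 2.22 in the last bin. The first 5 bins were covered over 31.0% ± 1.28 and the last 5 bins over 72.0% ± 2.19. The difference of 41.0 percentage points ± 0.906 was larger than the spread between the replicates. Exons other than the first were covered over 75.7% ± 2.11 of their bases and introns over 50.2% ± 2.08. That difference, 25.4 percentage points ± 0.0305, also exceeded the spread. Leaving out last exons as well, an alternative chosen after seeing the data, gave 35.98 points. Exons and introns were not matched on position, and first introns, near the poorly covered 5′ end, were kept. An exon preference therefore cannot be separated here from the climb toward the 3′ end.

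**Figure D1:**
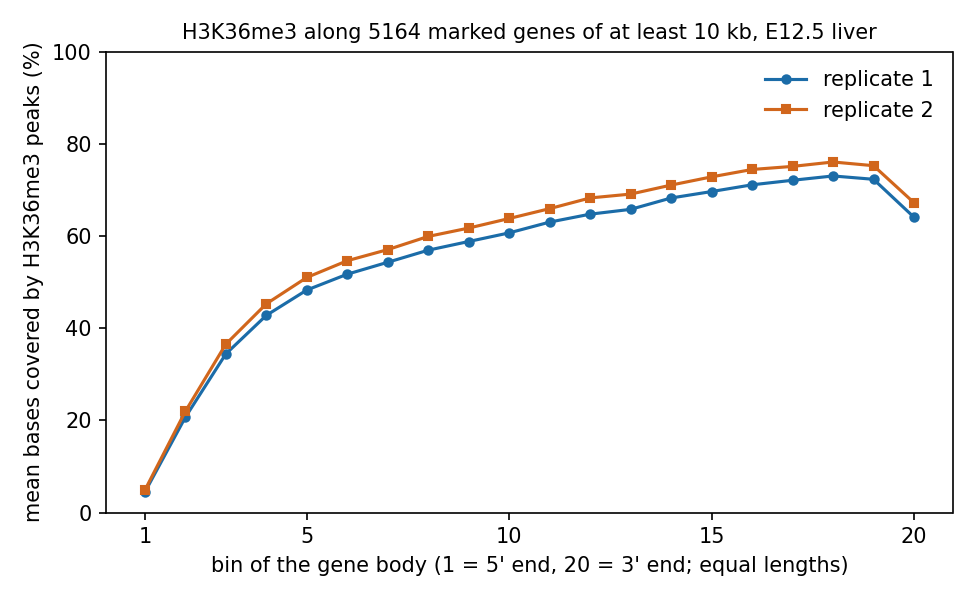
The plot shows the mean percent of bases covered by H3K36me3 peaks (vertical axis) in each of 20 equal bins from the 5′ to the 3′ end of the gene body (horizontal axis), for 5164 marked genes of at least 10 kb, with 1 line per replicate. Mean coverage of the replicates climbs from 4.63% in bin 1 to 74.5% in bin 18 and is 65.6% in bin 20.

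In all, 7015 of 21938 protein-coding genes (32.0%) were marked in both replicates, and 10587 had no covered base in either. A further 108 genes passed 20% in replicate 1 alone and 289 in replicate 2 alone. By the mean over the replicates, the 10 genes with the highest coverage weighted by fold were led by Ccnf. Its lead over the next genes was smaller than its SD, so their order is uncertain. This gene, on chromosome 17 (24222198 to 24251484), had a fold-weighted coverage of 15.2 ± 6.11 (SD, n = 2) with 92.8% ± 0.502 of its body covered. Top2a had 14.7 ± 2.57 and Zfp335 14.7 ± 1.39. The other 7 were Ttll12, Thoc3 (mRNA export), Pcif1 (a methyltransferase of the mRNA cap), Aurka (a mitotic kinase), Ddx17 (an RNA helicase), Eif4g2 (a translation factor) and Atxn2l, from 13.5 ± 3.06 for Ttll12 to 11.7 ± 1.51 for Atxn2l. Zfp335 and Pcif1 overlap at their 3′ ends on chromosome 2, so coverage there counts for both and they are not separate loci. A peak has a single fold for its whole length, and folds differed more between the replicates than coverage did. Coverage by itself was close, with 93.3% ± 0.646 for Aurka and 84.0% ± 0.247 for Atxn2l.

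Of 34 gene lists fixed before the data were examined, 11 were marked more often than genes of the same length and 20 less often (two-sided permutation tests with 10000 random lists matched on gene length, Benjamini-Hochberg adjusted over the 34 lists). Among the 8 lists of liver cell types, the erythroid list alone was marked more often. Of its 35 members, 28 were marked where 11.3 were expected (adjusted permutation p = 0.000227). Epb42, which encodes a membrane skeleton protein of the red cell, was covered over 90.3% ± 0.405 of its body (SD, n = 2) on chromosome 2 (121017891 to 121037072). Tfrc, the transferrin receptor, was covered over 88.7% ± 3.95 on chromosome 16 (32608920 to 32632794). The lowest member by the fixed rule was Hba-a1, an adult alpha-globin gene on chromosome 11 (32283511 to 32284465), with 0% in both replicates. All 7 unmarked members were globin genes, namely Hba-a1, Hba-a2, Hba-x, Hbb-bs, Hbb-bt, Hbb-y and Hbb-bh1, none of them with a covered base. The last 6 were named after their values were seen. These genes are 0.81 to 1.72 kb long, and only 4.01% and 17.3% of all genes in their 2 length classes were marked. Hba-a1 and Hba-a2 are near-identical copies, so the value for either is uncertain. The haem synthesis and iron list, which shares 5 members with the erythroid list, had 21 of 23 marked against 8.64 expected (adjusted permutation p = 0.000227). Its lowest member was the X-linked Abcb7, a mitochondrial transporter, at 1.203% ± 0.420. This gene is 133 kb long, and 16.7% of all genes in its length class were marked.

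**Figure D2:**
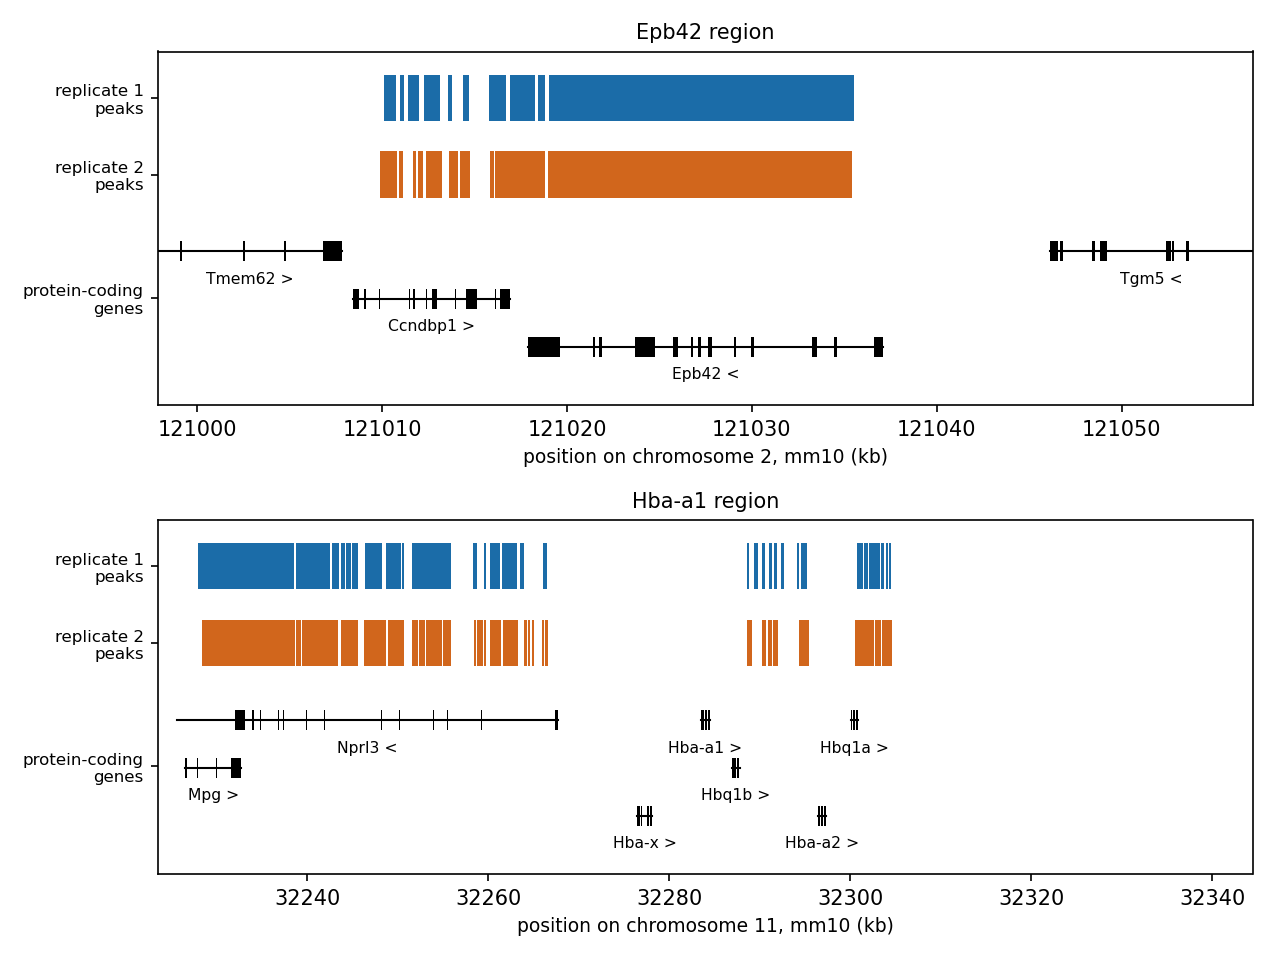
The map shows H3K36me3 peaks of each replicate (coloured blocks) above protein-coding genes (lines, with exons as black boxes and arrowheads for strand) around the most and least covered erythroid genes by the fixed rule, with position on the chromosome in kb (mm10) on the horizontal axis. Peaks cover 90.3% of Epb42 and none of Hba-a1, Hba-a2 or Hba-x.

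Genes of basic cell processes were marked in large majorities. Each gene class marked more often than length-matched genes had an adjusted permutation p of 0.000227. The replication and cell cycle list had 40 of 41 members marked against 15.3 expected, led by Top2a at 96.6% ± 0.643 (SD, n = 2). The exception was Pola1, the X-linked catalytic subunit of DNA polymerase alpha, at 9.86% ± 1.72. This gene is 327 kb long, and only 3.47% of all genes in its length class were marked. Among ribosomal protein genes 72 of 75 were marked against 17.6 expected, with Rps15a highest at 91.8% ± 0.533 and the short gene Rpl41 lowest at 7.55% ± 10.7. Marked shares were 67 of 75 for the mitochondrial ribosome, 66 of 80 for the respiratory chain, 32 of 39 for the proteasome, 49 of 52 for splicing and RNA polymerase II, and 33 of 35 for glycolysis and the citrate cycle. The most covered were Mrpl22 (81.5% ± 0.581), Atp5b (85.4% ± 0.189), Psmc4 (89.4% ± 0.489), Sf3a1 (95.9% ± 0.108) and Gpi1 (92.7% ± 0.685). The lowest members included Cox4i2 and Psma8, an isoform gene used in testis, with 0% in both replicates, and Pfkp, the platelet phosphofructokinase, at 5.13% ± 0.148. Genes that write, read or erase H3K36 methylation were marked in 22 of 25 cases against 9.15 expected. Kdm4a, a demethylase, was highest at 90.8% ± 1.33, and Kdm2b lowest at 9.13% ± 1.90. Zinc finger genes of the Zfp series were marked in a smaller share, 196 of 365 against 141 expected. Zfp869 was covered over 99.2% ± 1.19 and Zfp114 over 0%. At a threshold of 40% of the body covered, the zinc finger list was no longer called (adjusted permutation p = 0.0586).

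Markers of the other liver cell types were mostly unmarked. The fetal hepatoblast list had 3 of 36 members marked against 12.2 expected (adjusted permutation p = 0.00197). Taken singly, replicate 1 had 3 members past 20% and replicate 2 had 5, and the list was called with either left out (adjusted permutation p = 0.00993 without replicate 1 and 0.00221 without replicate 2). Serpinf2 (alpha-2-antiplasmin), on chromosome 11 (75431732 to 75439591), was covered over 47.2% ± 3.55 (SD, n = 2) and lies 1.35 kb from the marked gene Wdr81. Ambp was covered over 33.7% ± 5.28 (21.5% with −log10 p of at least 5), and the apolipoprotein gene Apoa1 over 0%. The third marked member, Krt18, at 25.2% ± 0.845, was named after its value was seen, as were Alb (albumin, 3.20% ± 0.666), Afp (alpha-fetoprotein, 0.619% ± 0.876) and the regulator Hnf4a (3.28% ± 0.513). Blood stem and progenitor genes were marked in 7 of 20 cases against 5.96 expected, which did not pass (adjusted permutation p = 0.624). Gfi1b, at 73.7% ± 0.248, and Ikzf1 (Ikaros), at 66.5% ± 4.41, were the highest picks by the fixed rule, and Angpt1 was at 0%. Lmo2 (72.9% ± 3.08) and Lyl1 (68.2% ± 3.56), not picked by that rule and named after their values were seen, exceeded Ikzf1. However, Lmo2 has 62.5% of its body inside the marked gene 4931422A03Rik, and 82.0% of its covered bases lay in peaks reaching that gene. Megakaryocyte genes had 0 of 19 marked (adjusted permutation p = 0.00414), with Gp9 highest at 20.3% ± 10.5. Granulocyte and mast cell genes had 0 of 15 (adjusted permutation p = 0.0152) and stellate and mesenchymal genes 1 of 20 (Vim, 33.0% ± 3.45; adjusted permutation p = 0.00425). Macrophage genes had 1 of 21 marked (adjusted permutation p = 0.00898), which was Cd68 at 96.4% ± 0.765. All covered bases of Cd68 lay in peaks that reached into the neighbouring gene Eif4a1, 0.782 kb away. Endothelial genes had 2 of 20 marked (adjusted permutation p = 0.0301), Egfl7 at 31.3% ± 1.99 and Eng at 26.0% ± 1.36, with Cdh5 at 0%. Eng fell to 18.2%, below the cut, with −log10 p of at least 5. Without replicate 2 the macrophage call was lost (adjusted permutation p = 0.105), and without replicate 1 the endothelial call (adjusted permutation p = 0.159). The granulocyte call was lost when 40% of the body had to be covered (adjusted permutation p = 0.0565).

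Adult hepatocyte metabolism genes were marked in 2 of 35 cases against 13.1 expected (adjusted permutation p = 0.000227). These were Slc10a1, the bile acid uptake transporter, at 49.9% ± 0.506 (SD, n = 2), and Ass1 of the urea cycle at 26.8% ± 2.17. Ass1 depended on weak peaks, with 24.3% at −log10 q of at least 2 and 18.4%, below the cut, at −log10 p of at least 5. Slc10a1 lies 2.67 kb from the marked gene Srsf5, and 0% of its covered bases lay in peaks reaching that gene. Because broad domains are broken into many peaks, signal running over from Srsf5 is not excluded. Tested directly, the fetal hepatoblast list exceeded the adult list by 2.62 percentage points, which did not pass the two-sided permutation test (p = 1). The difference ran from −3.24 points with members of at least 10 kb, an alternative chosen after seeing the data, to 13.7 points with marking at 10% (permutation p = 0.190), and was 8.17 points without replicate 1 (permutation p = 0.430). None passed, so no order of the 2 lists can be given by their share of marked genes. Below that cut the lists differed, in values that were not tested. Members with no covered base were 9 of 36 in the fetal list and 28 of 35 in the adult list. The median member was covered over 4.51% and 0%.

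**Figure D3:**
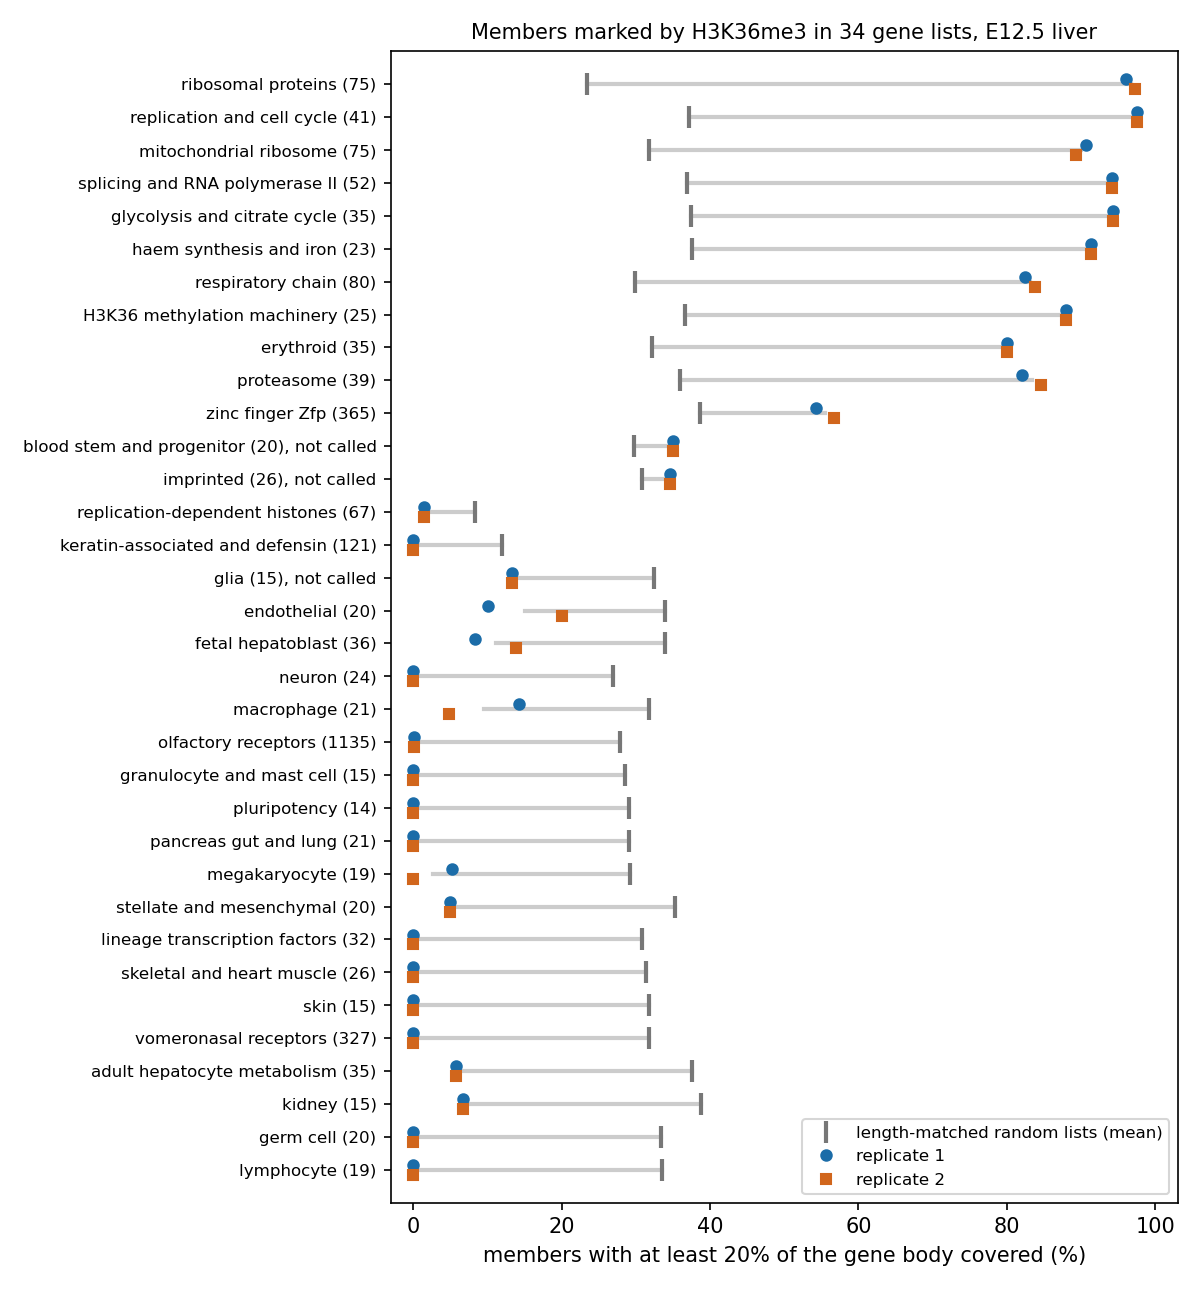
The plot shows the percent of members with at least 20% of the gene body covered (horizontal axis) in each of 34 gene lists (vertical axis, with the number of members), for replicate 1 (circles) and replicate 2 (squares). Grey ticks mark the mean of length-matched random lists for genes marked in both replicates, and grey bars join it to the mean of the replicates. Ribosomal protein genes lie at 96.0% and 97.3% against 23.5%, and the fetal hepatoblast list at 8.33% and 13.9% against 33.9%.

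Genes of tissues outside the liver carried almost no H3K36me3. Of the 9 lists, 8 were marked less often than length-matched genes. No member was marked among 24 neuronal genes (adjusted permutation p = 0.00372), 26 of skeletal and heart muscle (0.000755), 21 of pancreas, gut and lung (0.00357), 15 of skin (0.0101), 19 of lymphocytes (0.00402), 20 of germ cells (0.000755) or 14 of pluripotency (0.0145). Ttn (titin) was covered over 1.11% ± 0.0109 (SD, n = 2), Slc17a7, a vesicular glutamate transporter gene, over 1.64% ± 2.33, and Sftpb (surfactant protein B) over 19.3% ± 0.326. Kidney genes had 1 of 15 marked (adjusted permutation p = 0.0152). This was Slc5a2, at 25.5% ± 4.52, whose covered bases all lay in peaks reaching into the marked gene BC017158. Glia genes had 2 of 15 marked, Mbp at 22.4% ± 1.44 (15.3% with −log10 p of at least 5) and Cnp at 77.9% ± 2.34, and did not pass (adjusted permutation p = 0.156). Cnp, named after its value was seen, has 53.0% of its body inside the marked gene Dnajc7, and with such genes left out the glia list was called (adjusted permutation p = 0.0442). The skin and pluripotency calls were lost when 40% of the body had to be covered (adjusted permutation p = 0.0600 and 0.0554). Tested together, 42 of 186 genes of the liver lists were marked against 3 of 169 of the other tissues, a difference of 20.8 percentage points (two-sided permutation p = 1e-05, the smallest the resamples can give). Without the erythroid list, an alternative chosen after seeing the data, 14 of 151 were marked, 7 of them in the blood stem and progenitor list, and the difference was 7.496 points (permutation p = 0.0334). This call was lost with −log10 p of at least 5 (5.44 points, permutation p = 0.0599) and with marking at 40% (4.04 points, permutation p = 0.0713). The 7 stem and progenitor genes include Gfi1b, a factor of red cell and platelet precursors. Leaving out the erythroid list therefore need not remove all erythroid signal, and no difference was computed with both lists left out.

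Genes of chemosensory receptors, keratin-associated proteins and defensins, and lineage transcription factors of other organs were nearly free of called peaks. How the authors' alignment treated near-identical members of gene families is unknown here, so a lack of peaks in such families is not by itself a lack of the mark. Vomeronasal receptors had 0 of 327 marked and keratin-associated and defensin genes 0 of 121 (adjusted permutation p = 0.000227 for both). Lineage transcription factors of other organs, such as Ascl1 of neurons, had 0 of 32 marked (adjusted permutation p = 0.000755), and none of them had a covered base in either replicate. Olfactory receptors had 1 of 1135 marked (adjusted permutation p = 0.000227). This was Olfr419 on chromosome 1 (174248514 to 174252061), covered over 61.8% ± 3.21 (SD, n = 2), which lies 0.063 kb from the red cell spectrin gene Spta1. Of its covered bases, 0% lay in peaks that reached into Spta1. Since a broad domain is broken into many peaks, this does not exclude signal running over from Spta1. Replication-dependent histone genes, which are short, had 1 of 67 marked against 5.56 expected (adjusted permutation p = 0.0315). That member, Hist3h2a, at 30.9% ± 0.428, lies wholly within the marked gene Trim17 and was named after its value was seen. The histone call was lost at −log10 q of at least 2 (adjusted permutation p = 0.0540) and when only genes of at least 2 kb were kept (0.310). Imprinted genes, which are expressed from 1 parental allele, were marked in 9 of 26 cases against 8.003 expected (adjusted permutation p = 0.828). Impact was highest at 70.8% ± 5.07 and Magel2 lowest at 0%, and 2 members of the list are also in the hepatoblast list.

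The X chromosome had a smaller share of marked genes than any autosome. On X, 106 of 948 protein-coding genes (11.2%) were marked, against 6909 of 20807 (33.2%) on the autosomes. The difference was −22.0 percentage points (two-sided permutation p = 1e-05 within length classes, the smallest the resamples can give). Autosomes ranged from 24.5% on chromosome 14 to 40.2% on chromosome 8. By replicate, 11.4% and 12.8% of X genes passed 20% covered, against 33.7% and 34.5% of autosomal genes. Marked X genes had a median of 45.9% of the body covered and marked autosomal genes 58.4%. No gene on Y was marked. Both pools held embryos of both sexes, in proportions that the labels do not give.

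**Figure D4:**
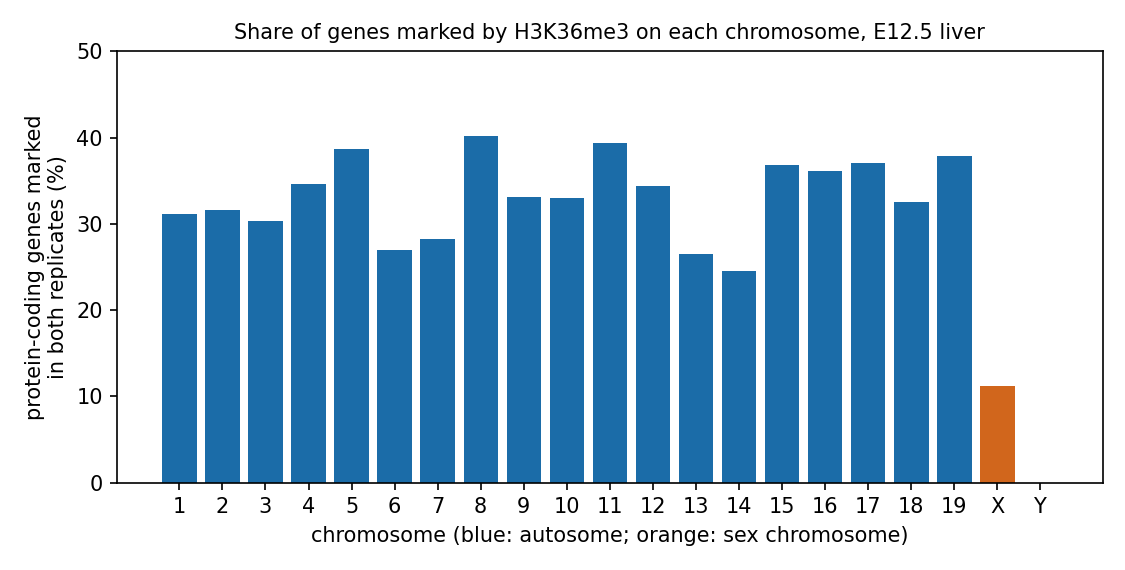
The bars show the percent of protein-coding genes marked in both replicates (vertical axis, from 0) on each mouse chromosome (horizontal axis), with autosomes in blue and sex chromosomes in orange. X lies at 11.2%, below every autosome (24.5% to 40.2%), and Y at 0%.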

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

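The test of X-linked members of the basic cell process lists was chosen only after the X result was seen, and so was the test on other liver cell types.

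Outside the chromosomes compared above, 18 peaks of replicate 1 and 21 of replicate 2 lay on scaffolds that are unplaced or have no position within their chromosome. They are listed because they exceed 3, the most that a count of 0 allows, and no expected number was derived. Their median fold was 2.97 and 3.33. Genes annotated as long noncoding or as provisional transcripts (type TEC) were also outside the main measurement, and 69 of 5499 such genes of at least 2 kb with no overlap with a protein-coding gene were covered over at least 20% in both replicates.

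Protein-coding genes on X were marked less often than autosomal ones, and no tested explanation was excluded. If the X merely held fewer housekeeping genes, X members of 8 lists of basic cell processes should be marked as often as autosomal members. The lists were haem synthesis and iron, replication, glycolysis, ribosomal proteins, mitochondrial ribosome, respiratory chain, proteasome and splicing. The haem list shares 5 members with the erythroid list, so not all are housekeeping genes. Of 14 X members 10 were marked (71.4%), against 370 of 406 (91.1%), a difference of −19.7 percentage points (permutation p = 0.0698), which lies beyond the 10 points allowed but rests on few genes. The p-value was taken within length classes, but the difference in points was not matched on length. The unmarked X members include the long genes Pola1 and Abcb7. If fewer X copies in male embryos only cost power to call peaks, fold enrichment over control should be no lower on X. The median fold of peaks in marked genes on X was 0.970 of that on autosomes in replicate 1 and 0.999 in replicate 2, neither above 1 nor 10% below it. Only called peaks in genes past the cut entered this ratio. Weak peaks lost on X would raise it, so it cannot decide. Both explanations, and a biological difference of the X in these embryos, which was not tested, therefore stay open.

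The low share of marked fetal hepatoblast genes, measured against genes of the same length, was not confined to short members. Of 21 members of at least 10 kb, 1 was marked against 8.20 expected (permutation p = 0.0009). A candidate explanation is that hepatoblasts are a minor share of the cells in the pools, so that much of their own mark is diluted below the peak threshold. The prediction set for it was that none of the 7 liver cell type lists besides the erythroid one would exceed length-matched genes, and the number that did was 0. These 7 include the hepatoblast list itself, and the others depend on the shares of their own cells, so the outcome cannot decide. Those calls had already been seen and do not measure the share of hepatoblasts. Of all 36 members, 9 had no covered base in either replicate, and the median member was covered over 4.51%. Among all 21938 protein-coding genes, 10587 had no covered base, a contrast that was not tested. A complete lack of called peaks thus does not describe most members. Dilution and a true scarcity of the mark on these genes cannot be told apart.

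The covered bases outside protein-coding genes, 6.60 Mb in replicate 1 and 6.96 Mb in replicate 2, lay mainly past gene ends, with 77.6% and 77.8% of them within 10 kb downstream of marked genes. Within 10 kb downstream of marked genes the covered bases outside genes were 4.39 times those within 10 kb upstream in replicate 1 and 4.46 times in replicate 2. Coverage inside the profiled marked genes was itself 65.6% in the last bin against 4.63% in the first, so peaks that merely run over gene edges also give a ratio above 1. Transcription past annotated ends and such spill therefore cannot be told apart. Other annotated genes held 16.9% of the covered bases outside protein-coding genes, 1.48 times the mean of shifted lists (11.4%, highest 13.3%), too few to account for most of them but more than chance placement gave.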

How the results depend on the processing

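The alternatives with first and last exons left out, without the erythroid list, with hepatocyte members of at least 10 kb and without X and Y genes were chosen after seeing the data. No paired analysis was possible because there was 1 group. Replicate overlap, genic share, liver against other tissues and X against autosomes kept their direction and side of the threshold under every alternative run, and the numbers of marked genes (5078 to 8181) and called lists (26 to 32) stayed within 1.5 times the main counts. The exon minus intron difference was 25.9 points without replicate 1, beyond the spread, and 25.4 without replicate 2, within it. Over 340 combinations of list and setting, 321 kept direction and side, 12 lost the call, 3 gained it and 4 changed sign. Of 92 named genes under 4 settings each, 338 values stayed within the spread and 30 moved, all under the 2 stricter peak thresholds and by at most 20.3 points (leaving out 1 of 2 replicates cannot move a mean by 1 SD). With −log10 p of at least 5, Ambp fell to 21.5%, and Ass1 (18.4%), Eng (18.2%) and Mbp (15.3%) fell below the 20% cut. Causes were not tested except where the setting itself gives fewer genes or stricter overlap. Depth is unknown here, and what it limits was not tested.

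Shared peaks were 71.0% with 50% of the peak overlapping and 48.7% with 50% of both. The rank correlation was 0.976 with −log10 q of at least 2, 0.971 with −log10 p of at least 5 and 0.985 for genes of at least 10 kb. The replicated share of pooled bases was 94.4% and 97.5% at those peak thresholds. The 3′ minus 5′ difference was 42.7 points with −log10 p of at least 5, 37.9 and 42.8 with marking at 10% and 40%, and 34.8 for genes of at least 30 kb. Exon minus intron was 25.5 points with −log10 q of at least 2, 28.8 and 18.4 with marking at 10% and 40%, 26.3 on the replicated list and 35.98 without first and last exons.

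Fetal minus adult hepatocyte changed sign, never near the threshold, at −0.159 points (−log10 q), −0.0794 (−log10 p and marking at 40%) and −3.24 (members of at least 10 kb). It grew to 8.17 without replicate 1 (2.62 without replicate 2), 13.7 with marking at 10% and 5.32 on the replicated list, and passed in none. Liver minus other tissues without the erythroid list lost the call with −log10 p of at least 5 (5.44 points, permutation p = 0.0599) and with marking at 40% (4.04 points, p = 0.0713).

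Observed minus expected shares of lists that changed, in points, were as follows. With −log10 q of at least 2, glia gained the call (−25.3) and histones lost it (−6.68). With −log10 p of at least 5, glia gained it (−23.4) and imprinted genes changed sign (−5.36). Marking at 10% lost endothelial (−20.3). Marking at 40% lost macrophage (−17.4), granulocyte (−21.2), skin (−23.3), pluripotency (−21.6) and zinc finger genes (4.57), and imprinted genes changed sign (−5.45). The replicated list lost macrophage (−20.1) and endothelial (−16.6). Over the replicates left out, endothelial ran from −24.3 to −15.4 and macrophage from −28.4 to −17.9. Without genes inside others, glia gained the call (−25.6), and stem and progenitor (−1.17) and imprinted genes (−0.128), called in neither case, changed sign. Genes of at least 2 kb lost histones (−17.9).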

Other observations

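Genes annotated as long noncoding or as provisional transcripts (type TEC) carried the mark in a small minority. Of 5499 such genes of at least 2 kb clear of protein-coding genes, 69 were marked (1.25%), 36 of them within 10 kb of a marked protein-coding gene and 33 farther away, and 5225 had no covered base. All genes named here were chosen after their values were seen. Mir17hg, the host gene of the miR-17-92 cluster, on chromosome 14 (115042879 to 115046727), was covered over 96.0% in replicate 1 and 100% in replicate 2. Malat1, an abundant nuclear RNA, had 72.8% ± 4.88 (SD, n = 2), and Snhg1 and Snhg17, hosts of small nucleolar RNAs, 76.0% ± 4.95 and 82.7% ± 0.987. Snhg1 lies 0.105 kb from the marked gene Slc3a2, so signal running over from it is not excluded. For Snhg17 the nearest marked protein-coding gene, Ralgapb, is 48.3 kb away. Lockd, 3.58 kb from Cdkn1b, a marked cell cycle inhibitor gene, had 62.3% ± 0.995. On X, Ftx, a neighbour of Xist, had 42.5% ± 1.19. The imprinted RNA gene H19 had no covered base, and Neat1 had 3.37% ± 0.531.

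At the globin genes, the nearest peak of the replicated list lay 1.09 kb from Hba-a2 and 3.87 kb from Hba-a1, but 372 to 412 kb from the 4 beta-like genes.

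Joining replicated peaks within 2 kb left 4 blocks outside every annotated gene with over 6 kb covered. The longest, on chromosome 4 (11174815 to 11186369), was covered over 86.0% ± 5.63 (SD, n = 2) and lay 0.435 kb from Trp53inp1, a stress-response gene. The others lay on chromosome 17 (36272572 to 36282949), 0.324 kb from Trim39, on chromosome 12 (108775971 to 108787457), 5.51 kb from Yy1, and on Y (90737730 to 90745929).

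The ratio of covered bases in replicate 2 to those in replicate 1 was 1.16 on X and 1.61 on Y (8.87 kb and 14.2 kb), against 1.05 on chromosome 5 to 1.08 on chromosome 14 among the autosomes.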
